A study of Mus musculus with 12 samples.

How the data were processed

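Livers were flash-frozen, total RNA was extracted, and stranded TruSeq libraries were made after depletion of ribosomal RNA with Ribo-Zero Gold, per the labels. The deposited table gives raw read counts per gene, made by the authors on genome build mm10 per the labels, with Ensembl identifiers and gene symbols. The aligner, the counting tool and the strand counted are not given in the sources used here. The same table holds FPKM values made by the authors, which equal the count scaled by the gene's bases and 1 total per sample, and these were not used here. The authors' log2 ratios, as deposited, are shrunken and give the first-named group over the second-named group. The authors' adjusted p is deposited as a score, -10 times its log10, in which 0 also stands for genes with no p. The other deposited column, Total BPs, gives the bases of each gene model per the file headers. The log2 ratios and scores were used only to set the authors' calls beside those made here. Of 16035 genes 15306 identifiers matched GENCODE release M21, and 1 was added to the starts in the table, which count from 0. 1 line of the table was empty and was left out.

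Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1, and figures were drawn in Python 3.11.15 with matplotlib 3.10.9 and pandas 2.3.3. Genes with low counts were removed with filterByExpr, which left 14725 and removed 1310. Libraries were scaled by TMM, with factors of 0.921 to 1.14, and 1 robust quasi-likelihood fit of 4 group means over all 12 libraries gave each comparison. The common biological coefficient of variation was 0.153. A Benjamini-Hochberg adjusted p under 0.05 was the threshold. The tests, the 32 gene lists, the rule for naming genes and the alternatives were chosen before the data were examined, except the test of the lists for the difference of the effects, its alternatives and those named below. Lists were tested with camera at a preset correlation of 0.01, beside camera with an estimated correlation and fry, which tests whether a list's genes move on balance one way and does not compare them with other genes. Counts of list members refer to members tested, which in some lists were few of those fixed, such as 3 of 12 neutrophil markers and 4 of 8 adipocyte genes.

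Genes were named by rule. It took the 8 largest rises and 8 largest falls of HFCF against chow at each month, among genes past the threshold with a mean of at least 5 CPM and no overlap between the 6 libraries. It took up to 4 members of each described list with the smallest p, and members past the threshold that moved against their list. It took the 5 genes with the smallest p in each direction for the other comparisons, and a set of genes of fibrosis, inflammation and lipid metabolism named in both months. Predicted genes without a gene symbol were counted and not named. Some genes that the rule names are not reported here. Several named genes overlap another annotated gene, among them Gstm6, Adora1, Ccnd3, Sulf2, Tgm2, Pptc7, Srebf1, Tm7sf2, Cpt1b, Acss2, Pltp, Cdc20, Ccnd1 and Acaa1b, and their counts are less certain.

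In a simulation, 100 genes per fold were changed 2-fold and 4-fold in counts of this depth and spread. The changed genes had a mean of at least 1 CPM, so the shares below do not cover genes with lower counts. At 1 month 80% of the 2-fold and 97% of the 4-fold changes were recovered over 14463 genes, and at 3 months 72% and 93% over 14463. For the difference of the effects the shares were 51% and 91% over 14452 genes, for chow over time 76% and 96% over 14506, and for HFCF over time 71% and 96% over 14442. False calls were 6 of 198 calls at 1 month, 13 of 192 at 3 months and 9 of 156 for the difference. They were 15 of 198 for chow over time and 3 of 185 for HFCF over time. Of 30 untouched lists 0 were called in each comparison. The simulated genes were drawn independently, so this does not test lists whose members move together. In the data the estimated correlation within the matrix list was 0.768 for HFCF against chow at 3 months.

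The alternatives were DESeq2 1.42.0 size factors, total library size alone, no filter on low counts, a mean of at least 1 CPM, the DESeq2 Wald test, limma-voom, a replicate block, only the 2 groups compared, robust estimation off, a fold change of at least 2, and leaving out each library in turn. Leaving out both libraries that stood apart was chosen after seeing the data. Spearman correlations between libraries were 0.959 to 0.993. No pair of libraries within a group was a duplicate, with a chi-square per gene of 14.2 to 72.3. Pairs across groups had no chi-square.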

Results

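Liver RNA of C57BL/6 mice was sequenced after 1 or 3 months on normal chow or on a diet named HFCF in the labels, which do not spell the name out. The series concerns the hepatic transcriptome in experimental nonalcoholic steatohepatitis. Each of the 4 groups held 3 biological replicates, giving 12 libraries. Mice fed for 1 month were 3 months old and mice fed for 3 months were 6 months old, so feeding time and age moved together. By these figures the age at the start of feeding differed as well. The libraries held 13733485 to 20277572 counts over 16035 listed genes, of which 14725 were tested. The male-linked transcript Ddx3y had 1708 to 2634 counts in each library, and Xist had 2 to 12. Means below are CPM, read counts scaled to library size, ± SD over 3 libraries, and changes are log2 fold changes ± SE from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, HFCF over chow unless stated. The SE was derived from that test, as the size of the change divided by the square root of the F statistic.

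The first principal component of log2 CPM held 42.7% of the variance and set the HFCF livers at 3 months apart from the other 9 libraries. Replicates 1 and 2 of that group lay at 60.7 and 63.8 on this axis, while replicate 3 lay at 29.3. Replicate 1 of chow at 1 month stood apart on the second component, at 36.8 against 0.01 and 6.44 for its group. HFCF at 1 month replicate 1 lay at -33.1 on that axis, against -18.5 and -17.3 for its group. HFCF at 3 months replicate 3 and chow at 1 month replicate 1 are called the libraries that stood apart and are named below beside the gene groups with which they moved.

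**Figure D1:**
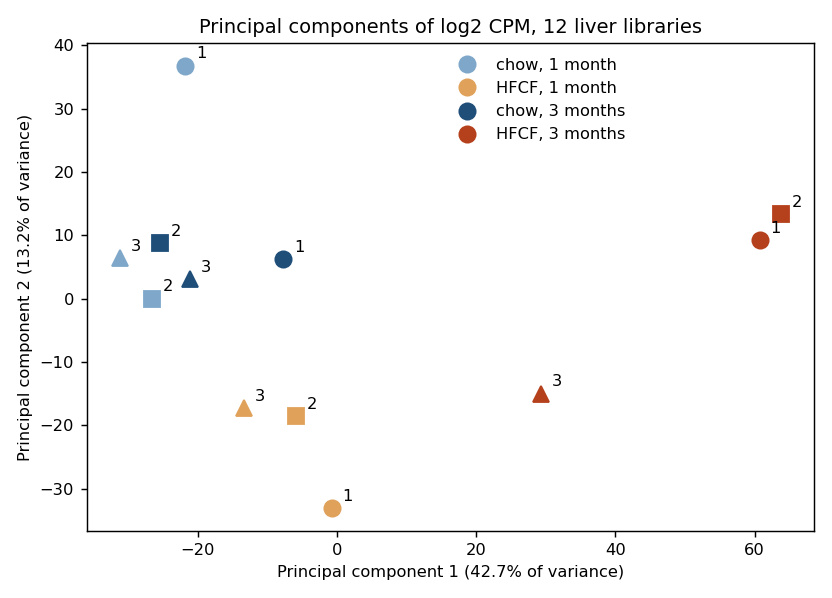
Principal components of log2 CPM over the genes tested, with 1 point per library, labelled by replicate number and coloured by group. The horizontal axis (42.7% of variance) places HFCF at 3 months at 29.3 to 63.8, and the vertical axis (13.2%) places chow at 1 month replicate 1 at 36.8.

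The comparison of HFCF with chow at 1 month asked which liver transcripts differed after the shorter feeding. Sqle, which encodes squalene epoxidase of the cholesterol pathway, fell from 26.9 ± 13.2 CPM in chow to 2.16 ± 0.62 CPM in HFCF, a change of -3.65 ± 0.41 (edgeR adjusted p = 0.00464). Scd1, the desaturase that makes monounsaturated fatty acids, rose from 1352 ± 212 to 6000 ± 3737 CPM (2.15 ± 0.35, edgeR adjusted p = 0.0126). Ppp1r3g, a glycogen-targeting subunit of protein phosphatase 1, rose from 1.40 ± 0.90 to 95.0 ± 48.0 CPM (6.09 ± 0.87, edgeR adjusted p = 0.0154). The xenobiotic cytochrome Cyp2b10 fell from 23.1 ± 16.8 to 0.937 ± 1.34 CPM (-4.67 ± 0.91, edgeR adjusted p = 0.0408), with 0 to 37 counts in the HFCF libraries. In mm10 coordinates, Sqle (ENSMUSG00000022351) lies on chromosome 15 from 59315077 to 59331192, Scd1 (ENSMUSG00000037071) on chromosome 19 from 44394451 to 44407709, Ppp1r3g (ENSMUSG00000050423) on chromosome 13 from 35958839 to 35970388 and Cyp2b10 (ENSMUSG00000030483) on chromosome 7 from 25897620 to 25926624. The other genes with the largest rises were Adam11, Osbpl3, Rnf186, Maff, Lamb3 and Tmem86a, at 1.94 to 2.39, and the other large falls were in the cell cycle inhibitor Cdkn1a (-4.21 ± 0.78), the ferritin receptor gene Scara5 (-2.42 ± 0.49), the clock gene Arntl (-2.35 ± 0.33), Fdps, Msmo1 and Cyp51.

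At this month 301 of 14725 genes passed, 153 higher and 148 lower, of which 47 and 51 changed at least 2-fold. Without chow replicate 1, chow replicate 3 or HFCF replicate 1 the count was 73, 65 and 73, and it was 149 without both libraries that stood apart. The DESeq2 Wald test called 641. Of 42 named genes that passed at 1 month, 10 kept the call without each of the 6 libraries in turn: Adam11, Sqle, Arntl, Fdps, Mvd, Tm7sf2, Abcg5, Abcg8, Gys2 and Clock. The other 32 lost it without at least 1 library. The adjusted p reached 0.0644 for Scd1 and 0.064 for Tmem86a without chow replicate 3, and 0.0718 for Ppp1r3g, 0.193 for Osbpl3, 0.193 for Rnf186 and 0.133 for Lamb3 without chow replicate 1. It reached 0.0776 for Maff without chow replicate 3 and 0.13 for Cyp2b10, 0.153 for Cdkn1a, 0.17 for Scara5, 0.099 for Msmo1 and 0.0699 for Cyp51 without HFCF replicate 1.

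Sterol genes moved together at 1 month. In the list of cholesterol synthesis genes and targets of the sterol regulator SREBP2, 14 of 24 members fell and none rose, or 16 when adjusted over the list alone, with a median change of -0.83. Fdps (-2.32 ± 0.27), Mvd (-2.39 ± 0.33) and Tm7sf2 (-1.58 ± 0.21), enzymes of the mevalonate and sterol branches, had edgeR adjusted p of 0.00276, 0.00485 and 0.00558. The list had a camera adjusted p of 1.43e-34, and adjusted p = 0.0502 with an estimated correlation. Its median log2 CPM relative to the mean of both chow groups, called relative to chow below, was -0.53 in chow replicate 1, a library that stood apart. Among targets of the oxysterol receptor LXR and efflux genes, 2 of 10 rose, or 6 when adjusted over the list alone, with a median of 0.34: Abcg5 (1.35 ± 0.15, edgeR adjusted p = 0.00188) and Abcg8 (1.03 ± 0.17, edgeR adjusted p = 0.00931), which together form the sterol export pump of the hepatocyte. These 2 genes overlap in the annotation. The LXR list had a camera adjusted p of 8.28e-09, and adjusted p = 0.0502 with an estimated correlation.

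Fatty acid genes changed in part at 1 month. Among 23 targets of the fatty acid receptor PPAR-alpha, 4 rose, or 7 when adjusted over the list alone, with a median of 0.36: the carnitine palmitoyltransferase Cpt1b (1.02 ± 0.19), Ppara itself (0.80 ± 0.16), the fatty acid binding protein Fabp1 (1.27 ± 0.26) and the thiolase Acaa1b (1.33 ± 0.31). The edgeR adjusted p of these 4 genes lay between 0.0167 and 0.0476 and reached 0.0763, 0.106, 0.122 and 0.189 in that order without chow replicate 1, or for Fabp1 without HFCF replicate 1. The camera adjusted p was 5.76e-10, and adjusted p = 0.375 with an estimated correlation. In the lipid droplet list 1 of 18 genes rose, the fatty acid transporter Cd36 (0.98 ± 0.23, edgeR adjusted p = 0.0485, or 0.183 without HFCF replicate 1), and 2 when adjusted over the list alone. That list had a median of 0.49 and a camera adjusted p of 0.000104, and adjusted p = 0.266 with an estimated correlation. De novo lipogenesis was not called (camera adjusted p = 0.635): Scd1 and Fads2 (0.63 ± 0.13) rose while Acly (-0.41 ± 0.08) and Acss2 (-0.45 ± 0.09), which make acetyl-CoA, fell, and 3 genes were higher and 4 lower when adjusted over the list alone. Without 1 library the adjusted p reached 0.104 for Fads2 (chow replicate 1), and 0.11 for Acly and 0.119 for Acss2 (HFCF replicate 1). Srebf1 (0.84 ± 0.37, edgeR adjusted p = 0.3), Fasn (-1.39 ± 0.37, 0.105), Cidec (1.37 ± 0.59, 0.299), Cyp4a14 (0.28 ± 0.48, 0.836) and Fgf21 (0.35 ± 0.46, 0.774) did not pass.

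Interferon and stress response lists were called at 1 month, with few members past the all-gene threshold. Of 18 interferon-stimulated genes, Bst2 (0.82 ± 0.15, edgeR adjusted p = 0.0146) and Ifi44 (1.16 ± 0.27, edgeR adjusted p = 0.0436) rose, and 11 were higher and 1 lower when adjusted over the list alone. Their median was 0.71 (camera adjusted p = 1.69e-08, and adjusted p = 0.461 with an estimated correlation), and the libraries were uneven, with medians relative to chow of 1.13, 0.42 and -0.07 in HFCF replicates 1, 2 and 3. Of 16 genes of the unfolded protein and integrated stress response, the endoplasmic reticulum chaperones Hyou1 (-1.18 ± 0.23, edgeR adjusted p = 0.0258) and Hspa5 (-1.04 ± 0.22, edgeR adjusted p = 0.0336) fell, and 1 was higher and 7 lower when adjusted over the list alone (median -0.45, camera adjusted p = 3.08e-06, and adjusted p = 0.303 with an estimated correlation). Without 1 library the adjusted p reached 0.0708 for Bst2 and 0.121 for Hspa5 (chow replicate 3), and 0.196 for Ifi44 and 0.123 for Hyou1 (HFCF replicate 1). Liver glycogen synthase Gys2 (1.52 ± 0.21, edgeR adjusted p = 0.00541) and the insulin receptor substrate Irs2 (1.58 ± 0.27, edgeR adjusted p = 0.0171, or 0.0853 without chow replicate 1) rose in a glucose list that was not called (camera adjusted p = 0.146; 2 higher and 2 lower of 17 when adjusted over the list alone). In the clock list, also not called (camera adjusted p = 0.213), Arntl and Clock (-0.59 ± 0.09, edgeR adjusted p = 0.00616) fell and Nr1d2 rose (0.67 ± 0.14, edgeR adjusted p = 0.0311, or 0.124 without chow replicate 1), with 7 higher and 3 lower of 17 when adjusted over the list alone.

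The remaining lists called by camera at 1 month had few or no members past the all-gene threshold. Resident Kupffer cell markers, of liver macrophages, had a median of 0.59 with none of 12 past the all-gene threshold and 3 higher when adjusted over the list alone (camera adjusted p = 0.000141, and adjusted p = 0.559 with an estimated correlation). The median relative to chow was 0.99, -0.06 and 0.67 in HFCF replicates 1, 2 and 3. Hepatocyte identity genes had a median of -0.21 with none of 18 past it and 2 lower when adjusted over the list alone (camera adjusted p = 0.00277, and adjusted p = 0.559 with an estimated correlation). That list had a camera adjusted p of 0.0823 without chow replicate 1, and Alb, which encodes albumin, did not pass (-0.39 ± 0.21, edgeR adjusted p = 0.388). The xenobiotic list (Cyp2b10 and Cyp3a11 lower, of 17), acute phase (none of 15), adipocyte genes (Lipe higher, of 4), bile acid genes (Abcb11 lower, of 19), female-biased genes (none of 7) and cytokines (Cxcl1 higher, of 17) had camera adjusted p of 0.0217 to 0.0405, and each rose past 0.05 without at least 1 library. Their adjusted p with an estimated correlation were 0.559, 0.625, 0.303, 0.559, 0.501 and 0.625 in that order. The highest values without 1 library were 0.116 for xenobiotic and 0.178 for bile acid genes (chow replicate 3), 0.555 for acute phase (HFCF replicate 3), 0.121 for adipocyte genes (HFCF replicate 2), and 0.198 for female-biased genes and 0.304 for cytokines (HFCF replicate 1). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, did not pass (-0.18 ± 0.36, edgeR adjusted p = 0.862). Without 1 library the adjusted p reached 0.193 for Cyp3a11 and 0.0648 for Cxcl1 (HFCF replicate 1), and 0.148 for Lipe and 0.197 for Abcb11 (chow replicate 1). When adjusted over the list alone, 3 xenobiotic genes, no acute phase gene, 1 adipocyte gene, 5 bile acid genes (1 higher, 4 lower), 2 female-biased genes and 1 cytokine passed.

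Matrix and most other cell type lists were not called at 1 month. Some had few members tested: 3 of 12 neutrophil, 4 of 14 T and NK cell, 2 of 12 pancreas and 1 of 9 muscle markers. None of 25 matrix genes (median -0.21, camera adjusted p = 0.29), 17 stellate cell markers (-0.17, camera adjusted p = 0.597) or 15 lipid-associated macrophage markers (0.45, camera adjusted p = 0.139) passed, nor did any when adjusted over the list alone. Col1a1 (-0.43 ± 1.03, edgeR adjusted p = 0.885), Acta2 (-2.28 ± 1.07, edgeR adjusted p = 0.338), Trem2 (1.23, edgeR adjusted p = 0.486) and Gpnmb (-0.23, edgeR adjusted p = 0.96) did not pass. The matrix list stood higher in chow replicate 1, the library that stood apart, at 0.55 relative to chow. Neutrophil, B cell, cholangiocyte and red blood cell lists had camera adjusted p of 0.146, 0.0893, 0.177 and 0.132, and T and NK cell, endothelial, pancreas and muscle lists 0.992, 0.87, 0.8 and 0.597, with no member past the all-gene threshold. When adjusted over the list alone Krt23 was higher and Sox9 lower among cholangiocyte markers, and no member passed in the other 7 lists. The cholangiocyte median relative to chow was 0.75 in chow replicate 1, which stood apart, against -0.06 and -0.09 in chow replicates 2 and 3. Cell cycle genes (median 0.63, camera adjusted p = 0.137) had 3 members higher and 1 lower of 12 when adjusted over the list alone, and over all genes 1 lower, Rrm2 (-1.20 ± 0.25, edgeR adjusted p = 0.0262, or 0.0968 without HFCF replicate 1). NRF2 targets, male-biased and oncofetal genes had none over all genes, and when adjusted over the list alone 1 NRF2 target was lower, Gsta2 (camera adjusted p = 0.403, 0.635 and 0.494). The median and the test of the endothelial list differed in sign, as did the median and mean of the T and NK cell and lipogenesis lists.

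The comparison at 3 months asked the same after the longer feeding. Scd1 rose from 633 ± 39.7 to 14070 ± 3759 CPM, a change of 4.47 ± 0.39 (edgeR adjusted p = 0.000152). Cidea, a lipid droplet protein of fat tissue, had 2 to 5 counts in the chow libraries and 696, 923 and 143 in HFCF replicates 1, 2 and 3 (edgeR adjusted p = 0.00234). Mmp12, the macrophage elastase, rose from 0.655 ± 0.06 to 48.3 ± 36.6 CPM (6.19 ± 0.95, edgeR adjusted p = 0.0035), with 89 counts in replicate 3 against 1531 and 1538 in replicates 1 and 2. Sqle fell from 25.2 ± 2.47 to 2.71 ± 0.35 CPM (-3.21 ± 0.39, edgeR adjusted p = 0.000822), and Enho, which encodes the secreted peptide adropin, fell from 26.1 ± 3.92 to 1.81 ± 0.79 CPM (-3.90 ± 0.38, edgeR adjusted p = 0.000318). In mm10, Cidea (ENSMUSG00000024526) lies on chromosome 18 from 67343564 to 67367794 and Mmp12 (ENSMUSG00000049723) on chromosome 9 from 7344381 to 7369499. The other large rises were in the complement protease Cfd (6.94 ± 1.47), Ly6d (5.57 ± 0.99), the macrophage glycoprotein gene Gpnmb (5.29 ± 1.12), Themis (4.62 ± 0.80) and Adgrv1 (4.57 ± 0.41). The other large falls were in Cyp2b10 (-4.20 ± 0.90), Serpina1e (-4.05 ± 0.55), Eif4ebp3 (-3.49 ± 0.60), Mup11 (-3.29 ± 0.77), asparagine synthetase Asns (-3.07 ± 0.80) and Nnmt (-2.78 ± 0.41). Serpina1e, Mup11 and Cyp2b10 belong to families of similar sequences, and Enho and Eif4ebp3 overlap Dnaic1 and Ankhd1, so their values are less certain. Other named members of gene families with similar sequences, among them Cyp2b9, Cyp2a4, Gstm6 and the haemoglobin genes, carry the same doubt.

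At 3 months 2802 of 14725 genes passed, 1697 higher and 1105 lower, of which 797 and 219 changed at least 2-fold. The count was 1382 without chow replicate 2, 1776 without chow replicate 3, 1478 without HFCF replicate 1 and 1255 without HFCF replicate 2, against 3910 without both libraries that stood apart. Higher genes were 60.6% of calls, and 81.4% when libraries were scaled by total counts alone, which moved the median of all genes to 0.127 (log2). Of 110 named genes that passed at 3 months, 36 lost the call without at least 1 library and 74 did not, of which Timp1 had no test without HFCF replicate 1 or 2. The adjusted p reached 0.0654 for Cfd and 0.0604 for Gpnmb without chow replicate 2, 0.072 for Cyp2b10 without HFCF replicate 2, and 0.0732 for Mup11 and 0.104 for Asns without HFCF replicate 1.

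**Figure D2:**
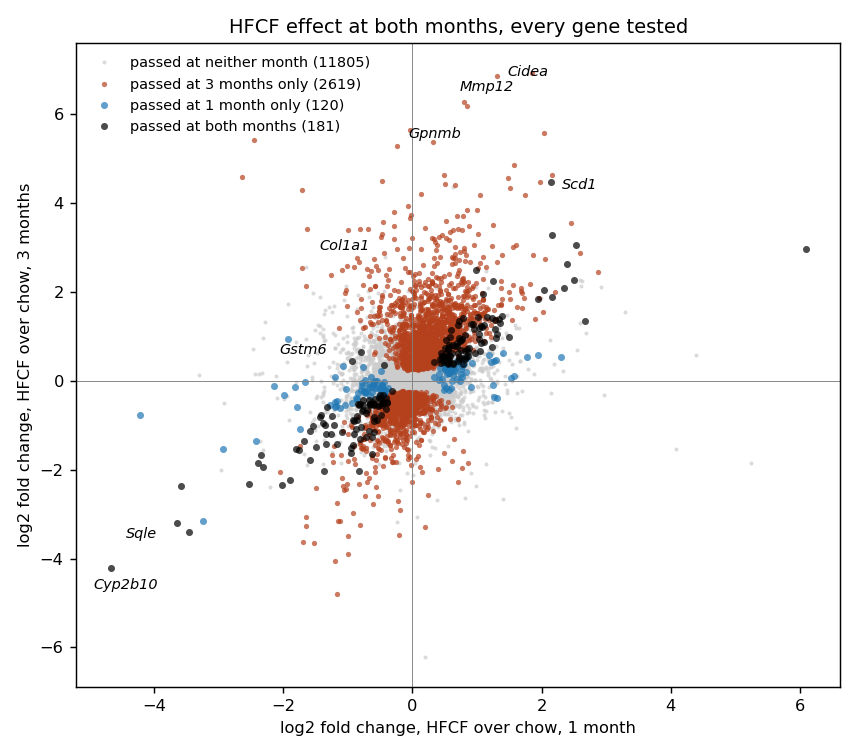
Log2 fold change of HFCF over chow at 1 month (horizontal) and 3 months (vertical), 1 point per gene tested, coloured by the months at which it passed an edgeR adjusted p of 0.05. There were 181 genes that passed at both months, 120 at 1 month alone and 2619 at 3 months alone, and labelled genes include Scd1, higher at both, and Sqle and Cyp2b10, lower at both.

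Markers of macrophages and of recruited myeloid cells rose at 3 months. Of 15 lipid-associated and recruited macrophage markers, 12 rose, or 13 when adjusted over the list alone, with a median of 3.03. Examples were the chemokine receptors Ccr2 (3.28 ± 0.39, edgeR adjusted p = 0.000523) and Cx3cr1 (3.40 ± 0.44, edgeR adjusted p = 0.000534) and the integrin Itgax (3.42 ± 0.56, edgeR adjusted p = 0.0026). Ly6c2 had 0 or 1 count in the chow libraries and 11 to 25 in HFCF (edgeR adjusted p = 0.00152), and Trem2 rose by 3.03 ± 0.67 (edgeR adjusted p = 0.0123, or 0.0608 without chow replicate 2). The list had a camera adjusted p of 1.52e-11, and adjusted p = 0.194 with an estimated correlation. Its median relative to chow was 2.72 and 3.25 in HFCF replicates 1 and 2 and 0.79 in replicate 3, the library that stood apart. Of 12 resident Kupffer cell markers 5 rose, or 6 when adjusted over the list alone, with a median of 0.78 (camera adjusted p = 0.0016, and adjusted p = 0.487 with an estimated correlation). The other 7 did not pass over all genes, and members ranged from -0.75 to 1.38. The Kupffer median relative to chow was 0.98, 0.76 and 0.59 in HFCF replicates 1, 2 and 3, and in the members called, replicate 3 lay 0.327 ± 0.083 (bootstrap SE) of the way from chow to the other replicates in CPM. The 5 genes were C1qa, C1qb, C1qc, Cd5l and Adgre1 (1.08 ± 0.31, edgeR adjusted p = 0.0371), each of which lost its call without at least 1 library, with adjusted p up to 0.126 for Adgre1 without chow replicate 2 and for C1qa without HFCF replicate 2. Clec4f did not pass (0.53 ± 0.23, edgeR adjusted p = 0.127). Liver libraries hold all cell types together, so resident and recruited macrophages were not told apart. Of 12 neutrophil markers in the list only 3 were tested, S100a8, S100a9 and Csf3r, and these rose (median 1.50, also 3 when adjusted over the list alone, camera adjusted p = 0.02, and adjusted p = 0.275 with an estimated correlation). Their adjusted p reached 0.118, 0.135 and 0.182 without 1 library, namely chow replicate 2 for the first pair and HFCF replicate 2 for Csf3r.

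Inflammatory and interferon genes rose with them. Of 17 cytokines, chemokines and innate sensors 11 rose, or 17 when adjusted over the list alone, with a median of 1.40 (camera adjusted p = 6.1e-12, and adjusted p = 0.144 with an estimated correlation). Cxcl1, a neutrophil chemokine, rose by 1.40 ± 0.20 (edgeR adjusted p = 0.000774) and the lipopeptide receptor Tlr2 by 1.50 ± 0.25 (edgeR adjusted p = 0.00161). The monocyte chemokine Ccl2 had 2 to 6 counts in chow and 159, 177 and 33 in HFCF replicates 1, 2 and 3 (edgeR adjusted p = 0.00167). Cxcl2 had 1 to 3 counts against 30, 29 and 13 (edgeR adjusted p = 0.00107), and Tnf had 0 to 6 against 45, 28 and 13 (edgeR adjusted p = 0.00688). Of 18 interferon-stimulated genes 12 rose, or 15 with 1 lower when adjusted over the list alone, with a median of 1.03 (camera adjusted p = 6.42e-11, and adjusted p = 0.237 with an estimated correlation). Examples were Bst2 (1.02 ± 0.15, edgeR adjusted p = 0.000861), Oasl2 (1.22 ± 0.20, edgeR adjusted p = 0.00163) and Ifit2 (1.77 ± 0.28, edgeR adjusted p = 0.00178). The interferon median was 1.11, 1.22 and 1.07 in HFCF replicates 1, 2 and 3, while that of the cytokine list was 1.76, 1.79 and 1.09.

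Matrix genes rose at 3 months, unevenly between libraries. Of 25 genes for collagens and matrix proteins 15 rose, or 23 when adjusted over the list alone, with a median of 1.46 (camera adjusted p = 2.6e-10, and adjusted p = 0.308 with an estimated correlation). Col14a1 rose by 1.28 ± 0.22 (edgeR adjusted p = 0.00265) and Lum, which encodes lumican, by 1.48 ± 0.30 (edgeR adjusted p = 0.00717). Timp1, the metalloproteinase inhibitor, had 1 count in each chow library and 65, 119 and 9 in HFCF replicates 1, 2 and 3 (edgeR adjusted p = 0.00197), and the collagenase Mmp13 had 0 to 3 against 174, 169 and 13 (edgeR adjusted p = 0.00215). Timp1 overlaps Syn1 in the annotation. Col1a1 did not pass (2.79 ± 0.99, edgeR adjusted p = 0.0845), at 3.25 ± 2.11 CPM in chow and 22.9 ± 16.3 CPM in HFCF. The list median relative to chow was 1.50, 1.91 and 0.26 in HFCF replicates 1, 2 and 3. Of 17 stellate cell markers, of the matrix-producing cells of the liver, 5 rose, among them the lectin Colec11 (0.87 ± 0.15, edgeR adjusted p = 0.00195) and the neurotrophin receptor Ngfr (1.28 ± 0.26, edgeR adjusted p = 0.00457), with 8 higher and 1 lower when adjusted over the list alone. Ecm1 fell (-0.60 ± 0.16, edgeR adjusted p = 0.0183, or 0.0868 without HFCF replicate 2) and Acta2, which encodes smooth muscle actin, did not pass (1.32 ± 1.04, edgeR adjusted p = 0.41). The stellate list had a median of 0.53 and a camera adjusted p of 0.0067, and adjusted p = 0.413 with an estimated correlation. Its median relative to chow was 0.56, 0.80 and 0.15 in the same 3 libraries.

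**Figure D3:**
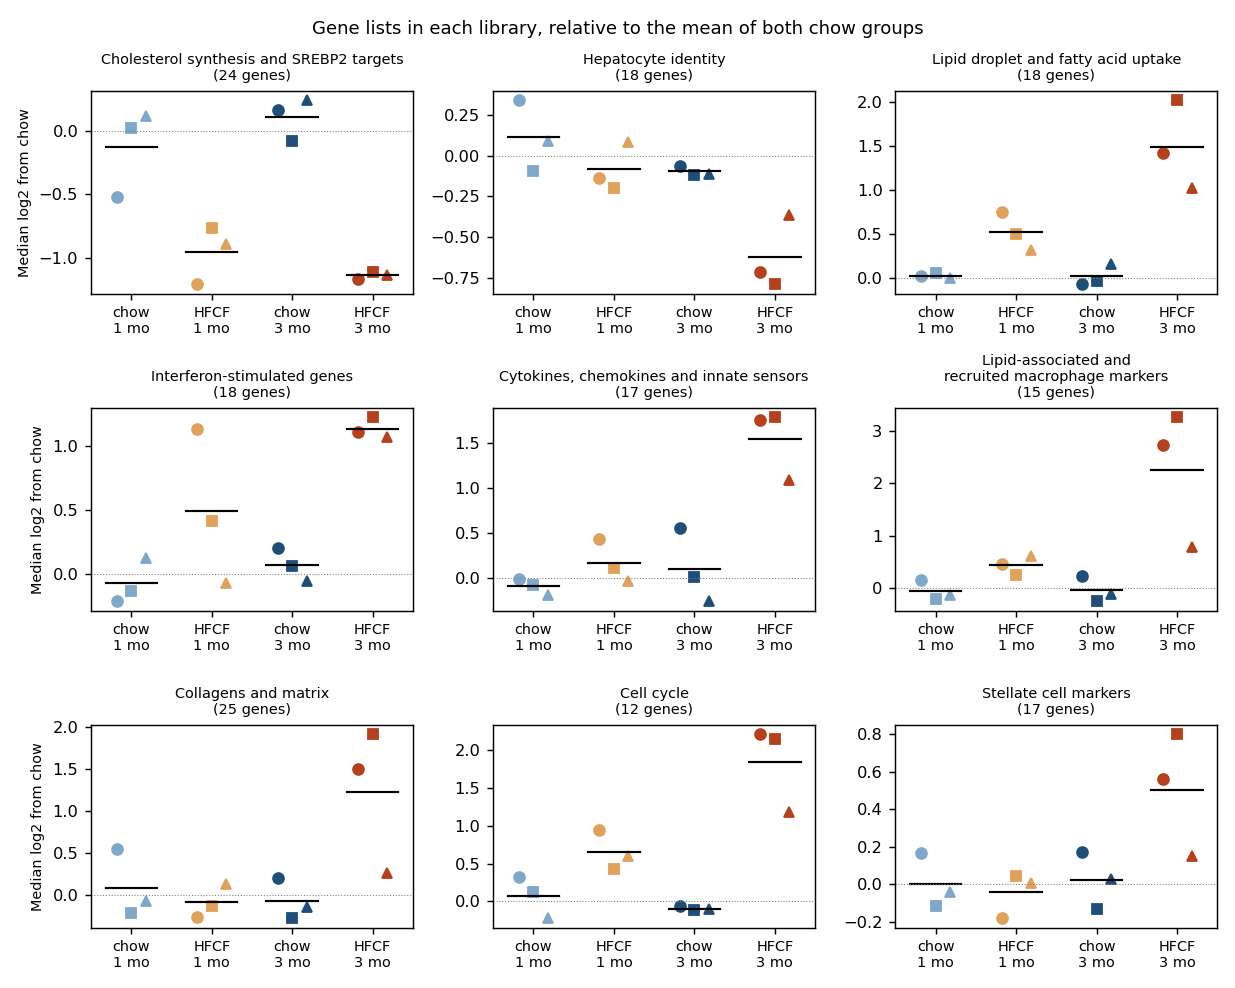
Median log2 CPM of the members of 9 gene lists in each library, relative to the mean of both chow groups, with circles, squares and triangles for replicates 1, 2 and 3 and a bar at the group mean. Cholesterol synthesis lies at -1.17, -1.11 and -1.14 in the 3 HFCF libraries at 3 months, while lipid-associated macrophage markers lie at 2.72, 3.25 and 0.79.

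Lipid storage genes rose and sterol synthesis genes fell at 3 months. Of 18 lipid droplet and fatty acid uptake genes 13 rose, or 14 with 1 lower when adjusted over the list alone, with a median of 1.65 (camera adjusted p = 5.69e-11, and adjusted p = 0.0631 with an estimated correlation). Cd36 rose from 95.1 ± 19.3 to 534 ± 61.0 CPM (2.49 ± 0.24, edgeR adjusted p = 0.000179), lipoprotein lipase Lpl by 2.22 ± 0.28 (edgeR adjusted p = 0.000921) and the acyltransferase Mogat1 by 2.66 ± 0.42 (edgeR adjusted p = 0.00173). Cidec rose by 2.10 ± 0.61 (edgeR adjusted p = 0.044, or 0.159 without HFCF replicate 2). Of 24 cholesterol genes 18 fell, or 20 when adjusted over the list alone, with a median of -1.22 (camera adjusted p = 2.84e-23, and adjusted p = 0.0941 with an estimated correlation). Lanosterol synthase Lss (-1.26 ± 0.15), Srebf2 (-1.07 ± 0.13), Dhcr7 (-1.42 ± 0.18) and Pmvk (-1.03 ± 0.14) had the smallest p. The cholesterol median was -1.17, -1.11 and -1.14 in HFCF replicates 1, 2 and 3. Of 10 LXR and efflux genes 5 rose, or 6 when adjusted over the list alone: Abcg5, Abcg8, Abcg1 (1.43 ± 0.19, edgeR adjusted p = 0.000591), Pltp and Lpcat3, the last chosen after its values were seen, with a list median of 0.45 (camera adjusted p = 1.5e-06, and adjusted p = 0.0631 with an estimated correlation). In de novo lipogenesis 7 of 19 genes rose, among them Scd1 and the regulator Srebf1 (2.03 ± 0.37, edgeR adjusted p = 0.00622), while Acly (-0.63 ± 0.08, edgeR adjusted p = 0.000523) and Acss2 (-0.47 ± 0.09, edgeR adjusted p = 0.00385) fell. Over the list alone 9 were higher and 2 lower, with a median of 0.39 (camera adjusted p = 0.018, or 0.096 without chow replicate 1, and adjusted p = 0.489 with an estimated correlation), and Fasn did not pass (-0.28 ± 0.37, edgeR adjusted p = 0.634). PPAR-alpha targets were not called (camera adjusted p = 0.0734): Cpt1b, Vnn1, Fabp1 and Acaa1b rose by 1.17 to 1.72 and Cyp4a31, chosen after its values were seen, fell (-1.06), with 6 higher and 1 lower of 23 when adjusted over the list alone. Ppara (0.48 ± 0.16, edgeR adjusted p = 0.0504), Cyp4a14 (-1.35 ± 0.49, 0.0822) and Fgf21 (1.02 ± 0.47, 0.156) did not pass.

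**Figure D4:**
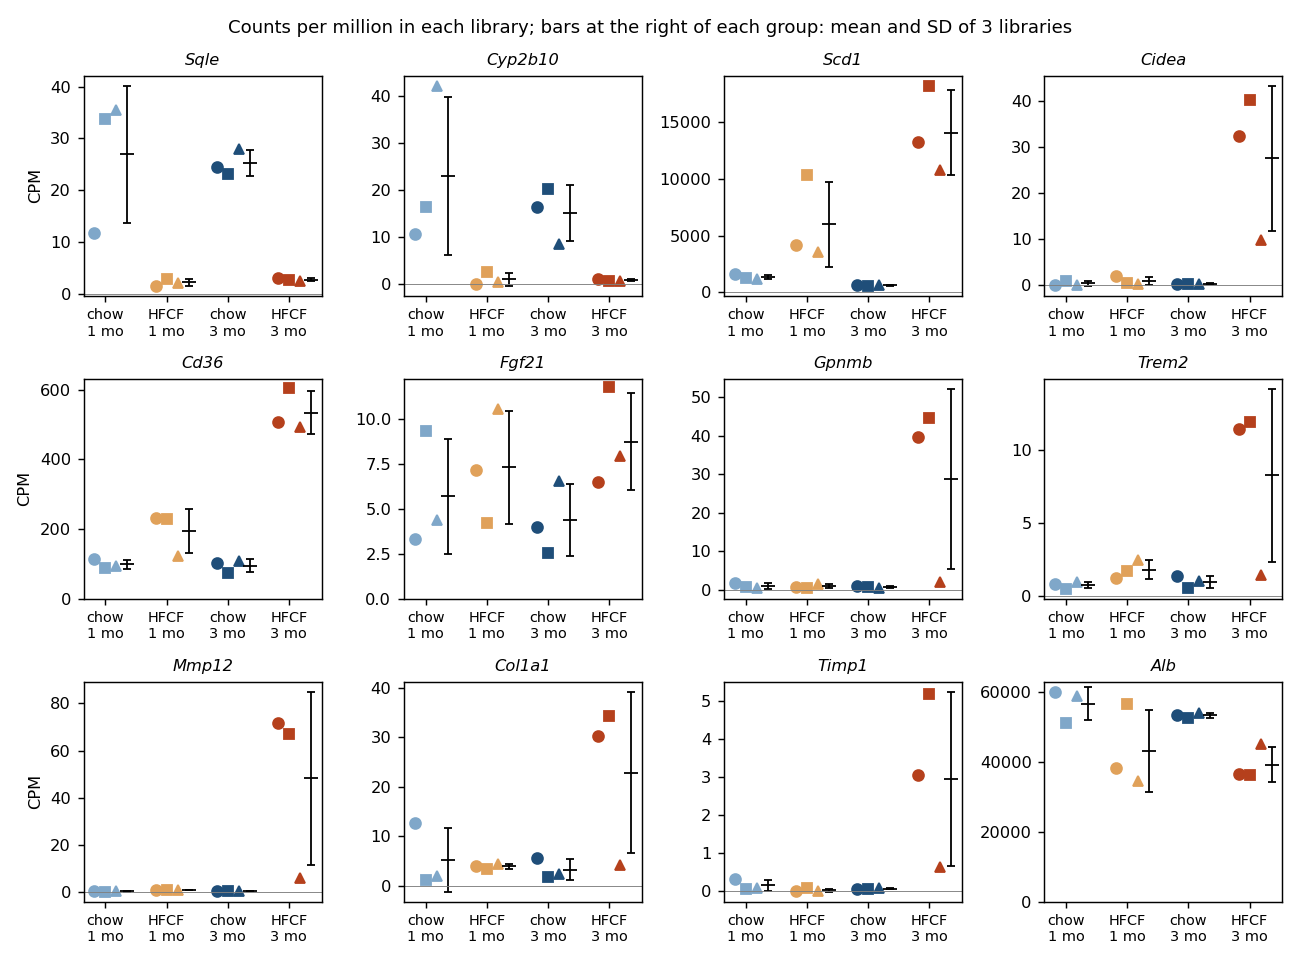
CPM of 12 named genes in each library (linear axes), with circles, squares and triangles for replicates 1, 2 and 3 and, to the right of each group, the mean and SD of 3 libraries. Mean Scd1 was 1352, 6000, 633 and 14070 CPM from left to right, and for Mmp12 the HFCF libraries at 3 months lie at 71.6, 67.1 and 6.14 CPM.

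Genes of hepatocyte metabolism fell at 3 months. Of 18 hepatocyte identity genes 8 fell, or 9 when adjusted over the list alone, with a median of -0.51 (camera adjusted p = 5.12e-07, and adjusted p = 0.237 with an estimated correlation). The urea cycle enzymes Arg1 (-1.51 ± 0.25, edgeR adjusted p = 0.00168), Cps1 (-1.72 ± 0.29, edgeR adjusted p = 0.00197) and Ass1 (-1.50 ± 0.28, edgeR adjusted p = 0.00405) and tyrosine aminotransferase Tat (-1.73 ± 0.30, edgeR adjusted p = 0.00243) fell, while Alb did not pass (-0.44 ± 0.21, edgeR adjusted p = 0.16). The hepatocyte median relative to chow was -0.72, -0.79 and -0.37 in HFCF replicates 1, 2 and 3. Of 17 glucose and fructose genes 5 fell and none rose, also 5 when adjusted over the list alone, with a median of -0.33 (camera adjusted p = 0.016, and adjusted p = 0.245 with an estimated correlation). Among them were Pck1, the gluconeogenic carboxykinase, which fell by 1.08 (edgeR adjusted p = 0.00434), the insulin receptor gene Insr (-0.48, edgeR adjusted p = 0.0148) and Tkfc (-1.20, edgeR adjusted p = 0.019), the latter pair with adjusted p of 0.0839 and 0.0766 without HFCF replicate 2. Of 11 male-biased liver genes Serpina1e, Cyp2d9 and Cyp7b1 fell (the adjusted p of the latter pair reached 0.0859 and 0.0934 without HFCF replicate 2; also 3 when adjusted over the list alone, median -0.18, camera adjusted p = 0.0312, or 0.309 without chow replicate 3, and adjusted p = 0.516 with an estimated correlation).

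Proliferation, oxidative stress and injury genes rose at 3 months. Of 12 cell cycle genes 8 rose, or 9 with 1 lower when adjusted over the list alone, with a median of 2.03 (camera adjusted p = 1.77e-07, and adjusted p = 0.208 with an estimated correlation). Cyclin D1 Ccnd1 rose by 2.08 ± 0.22 (edgeR adjusted p = 0.000274), Top2a by 2.71 ± 0.43 (edgeR adjusted p = 0.00162) and the proliferation marker Mki67 by 2.77 ± 0.43 (edgeR adjusted p = 0.00179), and Cdc20 had 1 to 3 counts in chow and 48, 58 and 13 in HFCF. Of 14 targets of the oxidative stress regulator NRF2, 6 rose, or 7 when adjusted over the list alone, with a median of 0.65 (camera adjusted p = 0.000441, and adjusted p = 0.263 with an estimated correlation), among them the glutathione synthesis gene Gclc (1.09 ± 0.15, edgeR adjusted p = 0.000609) and heme oxygenase Hmox1 (1.13 ± 0.19, edgeR adjusted p = 0.00243). The cell cycle median was 2.21, 2.15 and 1.18 and the NRF2 median 0.71, 1.03 and 0.08 in HFCF replicates 1, 2 and 3. Of 9 oncofetal and injury genes Anxa2 (3.40 ± 0.52, edgeR adjusted p = 0.0032), Ly6d, Golm1 and Cd24a rose, also 4 when adjusted over the list alone, with a median of 0.94 (camera adjusted p = 0.00347, and adjusted p = 0.263 with an estimated correlation). The oncofetal median was 0.92, 1.15 and 0.40 in the same 3 libraries. The adjusted p reached 0.0852 for Golm1 without HFCF replicate 2 and 0.155 for Cd24a without HFCF replicate 1. Of 4 adipocyte genes tested, from a list of 8, Cfd and Fabp4 rose, or 3 when adjusted over the list alone, with a median of 2.34 (camera adjusted p = 0.0119, and adjusted p = 0.144 with an estimated correlation). The adjusted p of Fabp4 reached 0.0827 without chow replicate 2.

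Several lists were not called at 3 months, some with few members tested (4 of 14 T and NK cell, 2 of 12 pancreas and 1 of 9 muscle markers). Those of T and NK cells (none of 4), B cells (Cd22 and Cd79b higher, of 6), endothelium (Tek higher, of 13), cholangiocytes (Krt23 higher, of 7), red blood cells (none of 6), exocrine pancreas (Cela1 higher, of 2) and skeletal muscle (none of 1), all markers of other cells that a piece of liver can hold, had camera adjusted p of 0.94, 0.135, 0.482, 0.188, 0.6, 0.528 and 0.482. In the bile acid list (camera adjusted p = 0.109) the sterol hydroxylase Cyp8b1 fell by 1.42 (edgeR adjusted p = 0.00126) with Cyp7b1, Baat, Slc10a1 and Slco1a4, and Hsd3b7 (chosen after its values were seen) and Abcb11 rose, while Cyp7a1 did not pass (-0.67 ± 0.37, edgeR adjusted p = 0.227). In the xenobiotic list (camera adjusted p = 0.199) Cyp3a13, Por and Cyp2b10 fell, and Cyp2b9 had 1 to 5 counts in chow and 443, 343 and 71 in HFCF. Acute phase (Hamp and Fgl1 lower), stress response (Chac1 and Atf3 higher, Asns and Hsp90b1 lower), clock (Arntl and Clock lower) and female-biased genes (Cyp2b9 and Cyp2a4 higher, Cux2 lower) had camera adjusted p of 0.482, 0.135, 0.94 and 0.793. Without chow replicate 2 the adjusted p reached 0.126 for Hamp and 0.0543 for Tek. It reached 0.0817 for Cd79b and 0.104 for Asns without HFCF replicate 1. Without HFCF replicate 2 it reached 0.0837 for Cd22, 0.153 for Fgl1, 0.0854 for Chac1, 0.129 for Atf3, 0.0789 for Hsp90b1, 0.0953 for Cyp2a4, 0.0951 for Baat, 0.098 for Slc10a1, 0.0934 for Cyp7b1 and 0.072 for Cyp2b10. When adjusted over the list alone, 3 bile acid genes were higher and 5 lower, 1 xenobiotic gene was higher and 3 lower, 2 clock genes were lower, and no acute phase gene passed. By the same adjustment 2 stress response genes were higher and 2 lower, as were 2 and 2 female-biased genes, and 2 B cell, 1 endothelial, 1 cholangiocyte and 1 pancreas gene were higher, with none in the T and NK cell, red blood cell and muscle lists. The median and the test of the acute phase, clock and T and NK cell lists differed in sign, as did the median and mean of the female-biased list.

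The genes changed at 1 month overlapped those changed at 3 months. Of 153 genes higher at 1 month 96 (62.7%) were also higher at 3 months, where independent lists would share 17.6 (Fisher's exact test across genes, p = 5.22e-52). Of 148 lower genes 82 (55.4%) were also lower, against 11.1 (Fisher's exact test, p = 2.99e-53). The 2 comparisons share no libraries, and genes are not independent replicates. Both come from 1 fit with the same estimate of each gene's spread, which can raise the overlap above that of independent lists. Across genes the log2 changes of the 2 months had r = 0.365. In 3 genes the calls went in opposite directions. Gstm6, a glutathione transferase, fell at 1 month (-0.94 ± 0.15, edgeR adjusted p = 0.00813) and rose at 3 months (0.45 ± 0.15, edgeR adjusted p = 0.0448). Adora1, an adenosine receptor gene, changed by -0.79 and 0.65, and the bile salt export pump Abcb11 by -0.45 and 0.35. At 1 month the adjusted p of Abcb11 reached 0.197 without chow replicate 1.

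The difference of the 2 effects was itself tested. Age and feeding time moved together here too, so it is not one of feeding time alone. It passed for 6 genes, 3 with a higher and 3 with a lower effect at 3 months, while 2296 genes had an unadjusted p under 0.05. Gstm6 (1.39 ± 0.21), the NF-kappaB inhibitor Tnfaip3 (2.17 ± 0.34) and Nes (1.89 ± 0.30), the last chosen after its values were seen, had the higher effect, with edgeR adjusted p of 0.0419, 0.0464 and 0.0464. Dact2 (-1.19 ± 0.17), cyclin D3 Ccnd3 (-0.87 ± 0.13) and the imprinted gene Peg3 (-1.61 ± 0.24) had the lower effect, each with edgeR adjusted p = 0.0419. The count was 878 without HFCF at 3 months replicate 3, 59 without HFCF at 1 month replicate 2, 3 (Adora1, Ildr2 and Peg3) without chow at 3 months replicate 1, 2 (Fam234b and Acnat2) without HFCF at 1 month replicate 1, 1 (Enho) without chow at 1 month replicate 1 and 0 without any of the other 7 libraries. Ildr2 and Fam234b were chosen after their values were seen. Gstm6, Tnfaip3, Dact2, Ccnd3 and Peg3 each reached an adjusted p of 0.148 without HFCF at 3 months replicate 1. The count was 367 by DESeq2. Etnk2, an ethanolamine kinase gene (-1.37 ± 0.22, edgeR adjusted p = 0.0514), and Adora1 (edgeR adjusted p = 0.0606) did not pass.

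Among the lists, camera called a difference of the 2 effects for 16, 11 with a higher and 5 with a lower effect at 3 months. The largest medians were 2.44 for lipid-associated macrophage markers and 1.86 for matrix genes, of which 7 of 15 and 18 of 25 passed when adjusted over the list alone and none over all genes (camera adjusted p = 4.93e-11 and 2.41e-15). None of the 16 held with an estimated correlation (adjusted p = 0.268 was the smallest). In libraries that stood apart, matrix genes had a median relative to chow of 0.55 in chow at 1 month replicate 1 (-0.21 and -0.07 in replicates 2 and 3) and 0.26 in HFCF at 3 months replicate 3 (1.50 and 1.91 in replicates 1 and 2), and macrophage markers had 0.79 in the latter (2.72 and 3.25). Cholesterol synthesis was not called (median -0.20, camera adjusted p = 0.17).

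The comparison of chow at 3 months with chow at 1 month gave 1 gene, Ciart, a repressor in the circadian clock, with 1190 genes at an unadjusted p under 0.05 and 69 genes called by DESeq2. Ciart (ENSMUSG00000038550, chromosome 3 from 95878503 to 95882251 in mm10) fell from 22.5 ± 5.26 to 4.67 ± 0.40 CPM (-2.26 ± 0.22, edgeR adjusted p = 0.00109), and its adjusted p was at most 0.0267 without any single library. Among the named genes, Sulf2 (-0.79 ± 0.11, edgeR adjusted p = 0.053) and the lipid transporter Abca3 (0.60 ± 0.09, edgeR adjusted p = 0.0651) did not pass. The counts were 6 without replicate 2 and 5 without replicate 3 of chow at 1 month, and 2 (Ciart and Mt2, the latter chosen after its values were seen) without replicate 1 of chow at 3 months. Those 6 were Ciart, Sulf2, Skil, Fam107a, Scara5 and Klhdc7a, and those 5 were Ciart, Sulf2, Abhd2, Hbb-bt and Hbb-bs, all but Ciart and Sulf2 chosen after their values were seen. Camera called 4 lists, with no member past the all-gene threshold. Medians were -0.22 for hepatocyte identity (camera adjusted p = 0.000933; 2 lower when adjusted over the list alone), 0.19 for cholesterol synthesis (camera adjusted p = 0.0132; 0), -0.77 for red blood cell genes (camera adjusted p = 1.98e-06; 5 of 6 lower) and -1.70 for the 1 skeletal muscle gene tested, Mylpf (camera adjusted p = 0.0194; 1 lower). None held with an estimated correlation (adjusted p = 0.382 was the smallest). Haemoglobin genes held 0.0218%, 0.0316% and 0.0126% of counts in chow at 1 month replicates 1, 2 and 3. They held 0.0126% to 0.0138% in chow at 3 months, so replicate 3 of chow at 1 month did not show the difference. In replicate 1 of chow at 1 month, which stood apart, the cholesterol list stood lower (-0.53), and the hepatocyte list (0.34) and Mylpf (1.10) stood higher, where replicates 2 and 3 had -0.10 and 0.09 for hepatocyte genes and 0.31 and 0.78 for Mylpf.

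The comparison of HFCF at 3 months with HFCF at 1 month gave 2385 genes, 1362 higher and 1023 lower at 3 months. Tgm2, a transglutaminase (1.31 ± 0.14), Maoa, a monoamine oxidase (1.16 ± 0.13), Gstm6 (1.31 ± 0.15), Nfe2l2, which encodes NRF2 (0.92 ± 0.11), and St6gal1 (1.06 ± 0.13) rose, and Etnk2 (-1.62 ± 0.16), Atp10d (-1.21 ± 0.12), Pptc7 (-1.32 ± 0.14), the kinase Map3k5 (-0.95 ± 0.10) and Tedc2 (-1.72 ± 0.18) fell, with edgeR adjusted p of 0.000511 to 0.000609. Camera called 15 lists. None of the lists held with an estimated correlation (adjusted p = 0.311 was the smallest). Higher at 3 months were, among others, 12 of 17 cytokines, 13 of 25 matrix genes, 11 of 15 lipid-associated macrophage markers and 9 of 14 NRF2 targets. Lower were 9 of 18 hepatocyte genes, 9 of 17 glucose genes (2 higher), 8 of 23 PPAR-alpha targets, 4 of 6 red blood cell genes (Hbb-bt, Hbb-bs, Hba-a1 and Hba-a2, median -0.96, camera adjusted p = 0.000758), 2 of 15 acute phase genes (Hamp and Fgl1, camera adjusted p = 0.0112) and 3 of 11 male-biased genes (Cyp7b1, Cyp4a12b and Serpina1e, with Cyp2u1 higher, camera adjusted p = 0.00715). When adjusted over the list alone these were 15, 22, 12, 10, 9, 9, 10, 5, 2 and 5. The genes named in the last 3 lists were chosen after their values were seen. HFCF at 3 months replicate 3 stood lower than replicates 1 and 2. Medians relative to the mean of both chow groups were 0.26 against 1.50 and 1.91 in matrix genes. They were 0.79 against 2.72 and 3.25 in lipid-associated macrophage markers and 0.08 against 0.71 and 1.03 in NRF2 targets. The count of genes was 1157 without HFCF at 1 month replicate 3, and 898 and 732 without HFCF at 3 months replicates 1 and 2. Higher genes were 57.1% of calls, and 87.6% of 3907 calls when libraries were scaled by total counts alone, which moved the median of all genes to 0.22.

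The authors' deposited table holds their own log2 ratios and adjusted p scores. At an adjusted p of 0.05 the authors' deposited table calls 628 genes at 1 month and 3091 at 3 months, and 297 of the 301 and 2701 of the 2802 genes called here are among them, each with the same sign. For HFCF at 3 months against 1 month the authors' deposited table calls 2756 genes, with 2294 of the 2385 called here, and for chow 62 genes, including Ciart. Mmp12 and Ccl2 have a score of 0 at 3 months in the authors' deposited table, which also stands for no p, with log2 ratios of 2.92 and 2.58 for HFCF over chow.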

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

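The tests on HFCF at 3 months replicate 3 and on chow at 1 month replicate 1, and the alternative without both of them, were chosen only after the results were seen.

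The effect of HFCF differed between 1 and 3 months, by a test of the difference itself, for 6 genes. The difference, 3 months minus 1 month in log2, was 1.39 for Gstm6, 2.17 for Tnfaip3, 1.89 for Nes (chosen after its values were seen), -1.19 for Dact2, -0.868 for Ccnd3 and -1.61 for Peg3. In 5 of 60 draws of the month within each diet, the real one included, as many genes were called (6 genes in the real draw, 412 in the highest other). The 4 other draws as large were among the 5 that kept the HFCF libraries of the 2 months apart. Those 5 draws keep the comparison of HFCF between months, in which 2385 genes differed, so they are not free of an effect. The 54 draws that mixed the months called 0 at most, but they put libraries that differ into the same group, which widens the spread. The draws therefore cannot decide on chance, which is not excluded. Without HFCF at 3 months replicate 3 the count was 878, and without HFCF at 1 month replicate 2 it was 59.

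The effect also differed, by camera, for 16 lists. The median of the difference was 1.86 for matrix genes, 0.634 for stellate cell markers, 2.44 for lipid-associated macrophage markers, 1.2 for cholangiocyte markers, -0.243 for hepatocyte identity, 0.140 for lipogenesis, -0.287 for PPAR-alpha targets and 0.722 for lipid droplet genes. The adjusted p with an estimated correlation was 0.312, 0.336, 0.312, 0.312, 0.522, 0.522, 0.651 and 0.268 in that order. The median was -0.500 for glucose metabolism, 0.298 for interferon-stimulated genes, 1.10 for cytokines, -1.19 for acute phase, 0.983 for NRF2 targets, 1.02 for cell cycle, -0.477 for male-biased genes and 0.972 for oncofetal genes. Their adjusted p with an estimated correlation was 0.268, 0.631, 0.312, 0.631, 0.312, 0.312, 0.631 and 0.312. The camera adjusted p rose past 0.05 without 1 library for 5 of these lists, at most to 0.42 for PPAR-alpha targets and 0.392 for male-biased genes (both without chow at 3 months replicate 3), 0.101 for lipogenesis (chow at 1 month replicate 2), and 0.234 for interferon-stimulated genes and 0.171 for acute phase (both HFCF at 1 month replicate 3).

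HFCF at 3 months replicate 3 lay between the other HFCF libraries of that month and chow. RNA of a chow liver mixed into it would move every list by the same share, if the rest resembled replicates 1 and 2. In CPM it had gone 1.07 ± 0.03 of the way in cholesterol synthesis genes (bootstrap SE) and 0.135 ± 0.064 in lipid-associated macrophage markers, a difference of 0.935 ± 0.070. These 2 lists lie near the ends of the shares and were picked after the results were seen. The SE covers genes of 1 library, so their difference cannot decide on mixing. Over all genes called, the median share was 0.502 in higher and 0.815 in lower genes, so the shares were unequal there too. Whether the rest of the RNA resembled replicates 1 and 2 was not tested. A swap with a 1-month HFCF library needs a partner out of place. Over all 412 tested members of the fixed lists, no library labelled HFCF at 1 month went further than 0.237 of the way from the others of its group to HFCF at 3 months replicates 1 and 2, against 0.504 for replicate 3, which argues against such a swap. A milder response of that animal may be an explanation, and it was not tested.

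Ciart was the gene called between chow at 3 months and chow at 1 month. Livers taken at another time of day could give this, with clock genes in phase with Ciart lower and those in antiphase higher at 3 months. The median change was 0.05 in the 9 in-phase genes and -0.20 in the 5 antiphase genes, a difference of 0.253 ± 0.278 (bootstrap SE over genes) where another time of day predicts a negative one. These 2 lists were set after Ciart was called. Members went both ways, from -0.32 (Per1) to 0.53 (Per3) in phase and from -0.40 (Arntl) to 0.66 (Npas2) in antiphase, which limits the test. In HFCF against chow at 1 month Ciart did not rise with the in-phase genes, whose median was 0.62, so they are an uncertain guide to Ciart. Ciart was also lower in HFCF at 3 months than at 1 month (-1.15, edgeR adjusted p = 0.00422), and age and feeding time, which moved together in both diets, stay open and untested.

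Connective tissue genes stood high in chow at 1 month replicate 1. Fibroblast markers lay 1.36 ± 0.39 (log2, bootstrap SE) above the other chow libraries of that month at the median, with 11 of 12 above 0, and 25 of 25 matrix genes lay above 0 with a median of 0.825. More connective tissue in that piece of liver is a candidate explanation and stays open, since the genes were picked for a pattern seen in 1 library. Activated stellate cells stay open as well, with an excess of 0.281 ± 0.190 in the stellate list. Smooth muscle genes were higher there by 2.3 ± 0.8 (3 of 4 above 0), cholangiocyte markers by 0.953 ± 0.580 (7 of 7) and hepatocyte identity genes by 0.43 ± 0.06, and mesothelium genes were lower, by -0.361 ± 0.248 (0 of 4 above 0).

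The splits of 6 libraries into 3 and 3 number 10, too few for a share under 0.05. As many genes as in the real split were called in 1 of the 10 splits for HFCF at 1 month (301, and 0 in the highest other), 1 for HFCF at 3 months (2802 and 0), 1 for chow over time (1 and 0) and 1 for HFCF over time (2385 and 5).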

How the results depend on the processing

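The alternative without both libraries that stood apart, and all alternatives for the lists of the difference, were chosen only after the results were seen. The other alternatives were planned. The cause of these changes was not tested, except that leaving out libraries leaves fewer samples. No called gene changed sign under any alternative run. With DESeq2 size factors chow over time had 2 genes (Ciart and Sulf2), as with no filter on low counts. With total library size alone the difference of the effects had 0 genes, chow over time 2 (Ciart and Abca3) and HFCF over time 3907. The DESeq2 Wald test called 641 genes for HFCF at 1 month, 367 for the difference and 69 for chow over time, and limma-voom called 3 for the difference (Gstm6, Ccnd3 and Dact2). With only the 2 groups compared the counts were 147 for HFCF at 1 month, 17 for chow over time and 1298 for HFCF over time. With at least a 2-fold change they were 98 at 1 month, 1016 at 3 months and 781 for HFCF over time.

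With the replicate block the difference had 48 genes. The 18 pairs of libraries that share a number had correlations of -0.173 to 0.19, of which 5 were over 0.1. In other groups, 5 libraries correlated best with one of their own number. This gave no clear sign that the numbers pair the samples, but with 3 libraries a group it cannot exclude it. Lists called with an estimated correlation were 0 at 1 month, 0 at 3 months and 0 for the difference, and fry called 2 at 1 month, 16 at 3 months and 0 for the difference. Without both libraries that stood apart there were 149 genes at 1 month, 635 for the difference, 2 for chow over time (Ciart and Sult1e1) and 3808 for HFCF over time. Leaving out each library in turn gave 65 (without chow at 1 month replicate 3) to 289 genes at 1 month, 1255 (without HFCF replicate 2) to 3631 at 3 months, 0 to 878 (without HFCF at 3 months replicate 3) for the difference, 1 to 6 (without chow at 1 month replicate 2) for chow over time and 732 (without HFCF at 3 months replicate 2) to 3562 for HFCF over time. Lists called at 1 month ranged from 9 (without chow replicate 2) to 14. The overlap was also run with a 2-fold minimum (57.4% of higher and 47.1% of lower genes shared), the replicate block (69.7% and 55.4%) and DESeq2 (54.9% and 51.3%). At this depth the simulation recovered 51% of 2-fold differences of the effects, in genes with a mean of at least 1 CPM.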

Other observations

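The gene lists in this part, and their tests, were chosen only after the results were seen.

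Genes of the urea cycle and amino acid breakdown were lower in HFCF at 3 months. Of 22 genes 14 fell and none rose, with a median log2 change of -0.87 (camera adjusted p = 7.62e-15 over 10 added lists, and adjusted p = 0.221 with an estimated correlation). Examples were argininosuccinate lyase Asl, Bhmt, which remethylates homocysteine, and the glycine methyltransferase Gnmt. At 1 month none of 22 passed, with a median of -0.40 (camera adjusted p = 8e-06, and adjusted p = 0.471 with an estimated correlation), and the difference of the effects had a median of -0.53 (camera adjusted p = 1.94e-07, and adjusted p = 0.384 with an estimated correlation). Actin cytoskeleton genes were higher at 3 months, 11 of 16 with a median of 1.32 (camera adjusted p = 3.08e-09, and adjusted p = 0.294 with an estimated correlation), among them Tmsb4x, Lgals1 and Anxa5.

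Of 25 lysosome genes at 3 months 10 rose, including the acid lipase Lipa and cathepsin S, Ctss, and 2 fell, Grn and Ctsl, with a median of 0.17 (camera adjusted p = 0.0161, and adjusted p = 0.352 with an estimated correlation). Of 15 coagulation genes Serpinf2, F7 and Plg fell, with a median of -0.26 (camera adjusted p = 0.000849, and adjusted p = 0.352 with an estimated correlation). Complement genes were not called (camera adjusted p = 0.172). Clock genes in phase with Ciart had a median of 0.62 in HFCF at 1 month, with 1 of 9 higher, Nr1d2 (camera adjusted p = 8e-06, and adjusted p = 0.287 with an estimated correlation). In the antiphase genes 2 of 5 fell, Arntl and Clock, with a median of -0.59 (camera adjusted p = 0.000152, and adjusted p = 0.287 with an estimated correlation). Livers of the 2 diets taken at another time of day could give such opposite shifts, and this was not tested. Ciart itself did not follow its in-phase genes, at 12.6, 18.9 and 11.9 CPM in HFCF and 23.9, 16.7 and 26.9 in chow at 1 month. Fibroblast markers at 3 months had a median of 1.00 with 2 of 12 higher, Mfap4 and Islr (camera adjusted p = 0.0258, and adjusted p = 0.562 with an estimated correlation).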
